A study of Mus musculus with 14 samples.

How the data were processed

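RNA was sequenced from primary mouse acute myeloid leukaemia cells, and 14 libraries were analysed. In these cells a Tet-Off vector carries MLL-AF9, a fusion oncogene that doxycycline switches off, together with a dsRED reporter, and another vector carries oncogenic NRAS and the Tet-Off activator. Per the labels' protocols, the leukaemias arose in irradiated mice that had received transduced foetal liver cells, the cells were taken from the spleens of sick animals, and the libraries were made from Trizol-extracted total RNA with an Illumina TruSeq V2 kit. The submitters' processing notes name CASAVA 1.8.2, TopHat2, HTSeq and limma and the genome build mm10, without saying which step each served.

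The authors deposited a table of log2 values for the doxycycline libraries and another for the transduced libraries, per the file headers and the values themselves. Each deposited log2 value is a log2 CPM (read counts scaled to a common library size) of the reads plus 0.5, over a scaled library size. This was read from the values: after removing that offset, 100% of the values in both tables came out as whole reads within 0.01 read. In both tables every gene had over 1 CPM in at least 2 libraries, so the authors had already left out low genes. The doxycycline table held 13419 entries, of which 13 repeated another, which left 13406 genes. There, 255 entries had no symbol and 19 had symbols turned into dates, and 260 entries were named by their identifiers from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. Of its identifiers, 13222 were found in that annotation. The table of the transduced libraries held 14563 genes, and 12647 genes were in both tables. Gene symbols are those of the tables, in which Kmt2a is listed as Mll1.

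The reads on the tabled genes came to 17922644 to 25959766 per library in the doxycycline table and 14051150 to 14948487 in the other. Intervals and detection floors given for reads cover counting error only, since reads without molecular identifiers are not independent molecules. The floor was 3 reads per library. The kit and the notes state no strand, so reads from overlapping genes on opposite strands cannot be told apart, and reads of paralogs and pseudogenes can be split between them by the counting. Replicates of a group differed by more than counting noise, and no library duplicated another. Nothing in the labels says that replicates of a group came from separate animals, so the p-values measure the spread between samples, which may be technical in part.

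Doxycycline libraries (n = 4) were compared with untreated libraries (n = 4), and Id2-GFP libraries (n = 3) with control-GFP libraries (n = 3), each within its own table, because the tables were normalized apart. The test was limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with moderated variances that follow the mean level (eBayes with a trend), a two-sided test and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. Fold changes are on the scale of the deposited log2 values, whose offset of 0.5 reads understates the change of low genes. For 29 gene lists, the count of members that passed was set beside limma's camera, a test of a list against all other genes, with a preset correlation between genes of 0.01. Camera was run for the lists with at least 5 measured members, and its p-values were adjusted over those lists. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance in 1 direction, were alternatives. Fry does not set a list against other genes, so lists that move no more than other genes can pass it. Id2, Mllt3, Mll1 and Nras were also compared with exact two-sided permutation tests, as a family of 8 tests. These ignored the pairing of the libraries described below. The 200 genes with the smallest p in each direction after doxycycline were tested in the other table with camera. Overlaps of genes were tested with Fisher's exact test. The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

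Named genes are Id1, Id2, Id3, Tcf3, Tcf4, Tcf12, Hoxa9, Meis1, Myb, Myc, Mllt3, Mll1 and Nras in both comparisons, the 10 genes that rose and the 10 that fell most among genes past the threshold whose groups did not overlap, leaving out predicted, clone, mitochondrial and ribosomal protein genes, up to 4 members of each list with the smallest p, and up to 5 genes past the threshold in both comparisons in each combination of directions. Gm6175, and genes named for the fit with the replicate block beyond those shared by both comparisons, were chosen after their values were seen. A few genes that this rule would name are not reported. Coordinates are from GENCODE M21 on GRCm38. The Gm6175 transcript was compared with Id2 transcripts using blastn 2.17.0. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.

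The titles give the doxycycline and untreated libraries the same 4 identifiers, and the Id2-GFP and control-GFP libraries the same replicate numbers. Of the doxycycline titles 3 of 4 also end in "-R", which no untreated title does, and the identifiers begin with TRIMA1 in 1 pair and TRIMA2 in the other 3. The labels do not say what either means. The doxycycline library without that ending lay at 36.0 on the first principal component, among the other doxycycline libraries (35.1 to 45.5) and apart from the untreated ones (−44.1 to −30.4). The ending therefore does not account for the place of that library. With a single such library, its part in the others cannot be told apart from doxycycline. Whether these numbers pair the libraries was checked from the deviations of each library from its group mean. Across genes, same-numbered libraries correlated at 0.543, 0.494, 0.459 and 0.398 in the doxycycline table and at 0.502, 0.501 and 0.500 in the other, and each library correlated best with its own number. Both sets of libraries were therefore taken as paired, and the fit with the number as replicate block was fitted beside the unpaired fit. It gave 9326 genes after doxycycline and 35 after Id2.

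The procedure was tested on simulated data with 200 changed genes. At the spread of the doxycycline table (13406 genes) it recovered 57 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 5 false calls. At the spread of the other table (14563 genes) it recovered 10 of 67, 50 of 67 and 66 of 66, with 3 false calls. Every simulated gene had the same coefficient of variation, the median of abundant genes (5.95% and 18.2%). The simulated libraries had no pairs, and none stood apart. These shares therefore do not give the power in the real tables, where the spread differs between genes. Alternatives covered the replicate block, filters on low values, quantile normalization, median centring, the variance trend and prior, library weights, an added fold-change threshold, each library or pair left out, and the size of the withdrawal gene sets. Scaling by library totals or by median-of-ratios factors, voom weights on the recovered reads, blocks with a pair left out, and the withdrawal sets and overlaps without single libraries or a pair were added after seeing the data.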

Results

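Gene expression was measured by RNA sequencing in 14 libraries of mouse leukaemia cells driven by Tet-Off MLL-AF9 and oncogenic NRAS. In the first set, 4 libraries came from cells kept in doxycycline for 4 days in vitro, which switches MLL-AF9 off, and 4 from untreated cells. In the other set, 3 libraries came from cells transduced with an Id2-GFP retrovirus and 3 from cells given a control-GFP virus, all sorted for GFP 2 days after transduction. Depth was 17922644 to 25959766 reads per library in the first set and 14051150 to 14948487 in the other. Values are CPM, read counts scaled to a common library size, or log2 CPM, changes are log2 fold changes ± SE, and adjusted p-values are from limma.

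The first comparison asked which genes changed when doxycycline switched MLL-AF9 off. No library had doxycycline without that switch, so effects of the drug itself cannot be told apart from those of MLL-AF9 loss. After 4 days of doxycycline, transcripts of Mll1 and Mllt3, the genes whose products are joined in MLL-AF9, fell 27.9-fold and 75.1-fold. Hoxa9, Meis1 and Myb, transcription factors that sustain self-renewal in MLL-rearranged leukaemia, fell 3.82-fold, 5.46-fold and 7.05-fold. Of the gene lists, those of monocytes and macrophages, of the lysosome and of inflammatory signalling rose and those of MYC and ribosome biogenesis and of proliferation fell with a preset correlation between genes. Each lost its call with an estimated correlation (adjusted p = 0.214, 0.266, 0.107, 0.107 and 0.107). Of the proliferation genes, 39 fell and 4 rose. Id2, which encodes an inhibitor of E-protein transcription factors, rose 3.16-fold.

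Mll1 went from 3901 ± 1931 CPM (SD, n = 4) in untreated cells to 128 ± 13.2 CPM (n = 4) in doxycycline, and Mllt3 from 489 ± 255 to 5.85 ± 0.665 CPM. The changes were −4.80 ± 0.30 (adjusted p = 1.3e-06) for Mll1, at chromosome 9 from 44803355 to 44881296, and −6.23 ± 0.32 (adjusted p = 5.8e-07) for Mllt3, at chromosome 4 from 87769925 to 88033364. Reads on Mll1 ranged from 46130 to 152814 in untreated libraries and from 2237 to 3037 in doxycycline, and the table does not separate the cells' own transcripts from those of the vector. Nras, which the other vector carries, was at 722 ± 107 and 856 ± 23.7 CPM, with a change of 0.26 ± 0.10 (adjusted p = 0.041) and overlapping libraries. The Nras call was lost when any of 7 libraries was left out (adjusted p from 0.0551 to 0.0907), and with no variance trend (0.057). Its change was −0.03 under quantile normalization and 0.02 with library totals (adjusted p = 0.881). In exact two-sided permutation tests that ignored the pairing, Mll1, Mllt3 and Id2 each gave p = 0.0286. That is the smallest that 4 against 4 libraries allow, and it was 0.0762 after adjustment over the 8 tests. Exchanges within pairs only would be fewer, so the smallest p would then be larger. Nras gave an exact permutation p of 0.0857, adjusted to 0.16.

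In all, 8733 of 13406 genes passed the threshold (65.1%), of which 4198 rose and 4535 fell. Of these, 1360 rose and 695 fell at least 2-fold. The groups did not overlap for 8040 genes (60.0%), and the first principal component, which held 84.7% of the variance, parted the doxycycline from the untreated libraries. The share of calls that rose was 48.1% and depended on the scaling: with library totals in place of the authors' factors, 2702 genes rose and 6912 fell (28.1% rose), with the median of all genes at −0.27 instead of −0.03. Changes below are relative to the authors' scaling, whose factors were 1.07 to 1.1 in untreated libraries and 0.89 to 0.95 in doxycycline. The 10 most abundant genes took 3.53 to 4.07% of reads in untreated libraries and 6.57 to 9.15% in doxycycline, where Lyz2, the lysozyme of macrophages, alone took 2.03 to 2.99%.

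The 10 named genes with the largest rises included enzymes and receptors known from myeloid cells, a potassium channel and Ankrd66, and no test of a shared function was made on them. Pla2g7, a secreted phospholipase of macrophages at chromosome 17 from 43568098 to 43612201, went from 3.56 ± 2.02 to 140 ± 22.9 CPM, a change of 5.44 ± 0.33 (adjusted p = 1.1e-06). Mmp9, a gelatinase of neutrophils and macrophages, rose by 4.96 ± 0.45 to 1023 ± 359 CPM, and Anpep, the aminopeptidase CD13 of myeloid cells, by 4.75 ± 0.11 to 208 ± 16 CPM. Dcstamp, needed for fusion of osteoclasts, rose by 5.04 ± 0.79, Cd209a, a lectin of dendritic cells, by 4.89 ± 0.22, and Stfa2, a cysteine protease inhibitor of myeloid cells, by 4.83 ± 0.56. Sirpb1c and Sirpb1b, signal-regulatory proteins of myeloid cells whose close sequence similarity leaves their separate values uncertain, rose by 5.12 ± 0.45 and 4.92 ± 0.44. Kcnh1, a potassium channel, and Ankrd66 rose by 4.90 ± 0.64 and 4.74 ± 0.57, from 6 and 14 reads summed over the untreated libraries. The 10 genes had adjusted p-values of at most 3.5e-04 and were higher in 4 of 4 doxycycline libraries than in any untreated library.

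The genes that fell most were of mixed function, and no test of a shared function was made on them. Foxd1, a forkhead factor at chromosome 13 from 98354242 to 98359305, fell by 7.89 ± 0.75 on the log2 scale (adjusted p = 1.4e-05), from 1317 reads in the untreated libraries together to 4 in doxycycline. Irx5, an Iroquois homeobox factor, went from 467 to 10 reads, Slc35d3 from 288 to 11 and Skida1 from 3571 to 117. Rag2, which encodes part of the V(D)J recombinase, had 193 reads in untreated cells and 1 in doxycycline, a ratio of 174 per depth with a 95% counting interval of 30.9 to 6917. Klhl30, Sorcs2 and Car4 had 0 reads in all doxycycline libraries, so at the floor of 3 reads per library they were at least 7.84-fold, 6.21-fold and 6.60-fold lower. All 8 were lower in 4 of 4 doxycycline libraries, with limma adjusted p-values of at most 8.0e-04.

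Targets of MLL fusion proteins and stem-cell genes fell together. Of 29 measured genes of the MLL-AF9 programme, 23 fell and 1 rose (23 and 2 adjusted over the list alone), with a median change of −1.34 and camera adjusted p = 1.3e-06, or adjusted p = 0.107 with an estimated correlation. Hoxa9, at chromosome 6 from 52223100 to 52231089, went from 144 ± 13.9 to 37.8 ± 4.5 CPM, Meis1, at chromosome 11 from 18879817 to 19018985, from 68.9 ± 8.46 to 12.7 ± 2.37 CPM, and Myb, at chromosome 10 from 21124935 to 21160984, from 598 ± 41.6 to 85.1 ± 10.7 CPM. Their changes were −1.93 ± 0.10, −2.45 ± 0.13 and −2.82 ± 0.09, with adjusted p-values of 5.0e-07, 6.6e-07 and 1.9e-07. Cdk6, a cyclin-dependent kinase of early G1, and Arid2, a chromatin remodelling subunit, fell as well (−1.93 ± 0.08 and −1.16 ± 0.06). Of 23 stem and progenitor cell genes, 16 fell and 3 rose (the same counts adjusted over the list alone), with a median of −1.39 and camera adjusted p = 0.0012, or adjusted p = 0.439 with an estimated correlation. Angpt1, a ligand of the TEK receptor, and Etv6, a repressor needed by stem cells, fell (−3.94 ± 0.17 and −1.14 ± 0.06), whereas Cd93, a surface glycoprotein of progenitors and monocytes, rose by 1.16 ± 0.06.

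Monocyte and macrophage genes showed the opposite direction, with 36 of 39 higher and none lower (37 and 0 adjusted over the list alone). Their median change was 2.06 (camera adjusted p = 9.3e-13, or adjusted p = 0.214 with an estimated correlation). Gpnmb, a transmembrane glycoprotein of macrophages, went from 212 ± 50.9 to 2841 ± 395 CPM. Cd68 and Trem2, a lysosomal glycoprotein and a lipid-sensing receptor of macrophages, rose by 2.32 ± 0.10 and 3.09 ± 0.14. Of 35 phagosome and lysosome genes, 33 rose and 0 fell, also over the list alone, with a median of 1.12 (camera adjusted p = 7.5e-13, or adjusted p = 0.266 with an estimated correlation). These included the protease Ctsd, which went from 1043 ± 165 to 6705 ± 838 CPM, the dipeptidase Ctsc (1.44 ± 0.07), the phagocyte oxidase subunit Cybb (2.35 ± 0.10) and Tfeb (1.22 ± 0.06), a transcriptional regulator of lysosomal genes. Of 23 inflammatory cytokine and chemokine genes, 21 rose and 0 fell, also over the list alone, with a median of 2.05 (camera adjusted p = 8.4e-08, or adjusted p = 0.107 with an estimated correlation). Tnf rose by 2.05 ± 0.12, the chemokines Cxcl2 and Ccl6 by 4.26 ± 0.26 and 4.49 ± 0.31, and Il1rn, the antagonist of the interleukin-1 receptor, by 2.44 ± 0.18.

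Neutrophil genes moved in both directions: 23 of 32 rose and 6 fell, also over the list alone, with a median of 2.31 (camera adjusted p = 0.0015, or adjusted p = 0.554 with an estimated correlation). The lysozyme gene Lyz1 rose by 3.2 ± 0.27, the annexin Anxa1 by 1.73 ± 0.13 and Csf3r, the receptor for granulocyte colony-stimulating factor, by 1.64 ± 0.13, whereas Ctsg, a protease of the primary granules of immature cells, went from 1205 ± 186 to 228 ± 60.9 CPM. Reads on Lyz1 may be shared with the far more abundant lysozyme gene Lyz2, so the separate rise of Lyz1 is uncertain. Of 12 conventional dendritic cell genes, 7 rose and 2 fell, also over the list alone. This list, with a median of 0.95, passed narrowly (camera adjusted p = 0.0484, or adjusted p = 0.554 with an estimated correlation). Its call was lost with the replicate block (adjusted p = 0.0558) and without untreated replicate 4 (0.0804), doxycycline replicate 2 (0.0753) or doxycycline replicate 3 (0.0556). It was also lost without pair 4 (0.0773), with either floor on low values (0.0504 and 0.0629), median-of-ratios scaling (0.0581), no variance trend (0.0502) or array weights (0.0549). Relb, an NF-kB subunit, rose by 1.38 ± 0.11, and the surface proteins Slamf7 and Cd83 by 4.09 ± 0.49 and 3.39 ± 0.45.

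**Figure D1:**
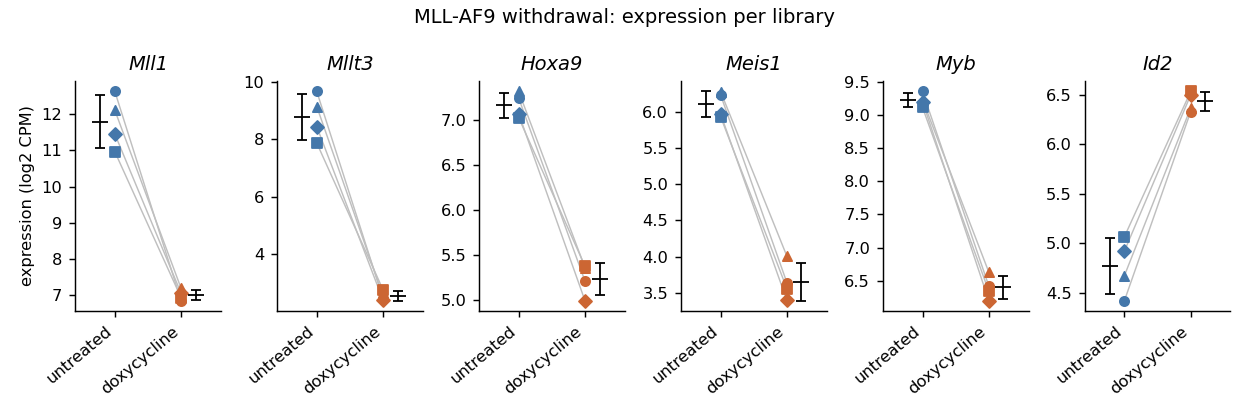
Expression of named genes in the 4 untreated and 4 doxycycline libraries, in log2 CPM on the vertical axis; each point is a library, marker shapes and grey lines join libraries with the same identifier, and bars beside the points are the mean ± SD. Id2 lies higher in 4 of 4 doxycycline libraries (6.43 ± 0.10 against 4.77 ± 0.28 log2 CPM), and Mll1, Mllt3, Hoxa9, Meis1 and Myb lie lower.

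Genes of growth and division were lower. All 40 measured MYC and ribosome biogenesis genes fell, also over the list alone, with a median of −0.90 (camera adjusted p = 1.5e-16, or adjusted p = 0.107 with an estimated correlation). Myc itself fell (−1.07 ± 0.10, adjusted p = 9.6e-06), as did Dkc1 and Nolc1, nucleolar proteins of ribosome assembly (−1.47 ± 0.05 and −1.14 ± 0.05), Srm, an enzyme of polyamine synthesis (−1.32 ± 0.05), and Cad, an enzyme of pyrimidine synthesis (−1.1 ± 0.04). Of 43 proliferation genes, 39 fell and 4 rose, also over the list alone, with a median of −0.55 (camera adjusted p = 2.7e-11, or adjusted p = 0.107 with an estimated correlation). The replication helicase subunits Mcm2 and Mcm3 fell (−1.19 ± 0.05 and −0.97 ± 0.04), and so did the licensing factor Cdc6 (−1.21 ± 0.05) and the transcription factor Mybl2 (−1.21 ± 0.05). Ccnd1, a G1 cyclin that is also in the list of RAS-ERK output, rose by 0.72 ± 0.06.

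Of 31 cell cycle inhibitor and apoptosis genes, 20 rose and 4 fell, also over the list alone, with a median of 0.72 (camera adjusted p = 4.8e-04, or adjusted p = 0.107 with an estimated correlation). Btg1 and Btg2, which restrain proliferation, rose by 1.23 ± 0.06 and 1.75 ± 0.10, and the survival genes Mcl1 and Bcl2l1 rose as well, by 1.02 ± 0.04 and 1.53 ± 0.10. Of 33 interferon response genes, 26 rose and 2 fell, also over the list alone, with a median of 0.71 (camera adjusted p = 8.1e-05, or adjusted p = 0.554 with an estimated correlation). Trim30a, Bst2 and Oas2 rose by 0.81 ± 0.08, 0.61 ± 0.07 and 1.16 ± 0.13, and Gbp3, a guanylate-binding protein, fell by 1.33 ± 0.15. Of 22 RAS-ERK output genes, 15 rose and 3 fell, also over the list alone, with a median of 0.95 (camera adjusted p = 0.0112, or adjusted p = 0.554 with an estimated correlation). Dusp6, an ERK phosphatase, rose by 1.24 ± 0.08, Lif, a cytokine, by 2.93 ± 0.20 and Ier3 by 1.66 ± 0.15. Of 23 immediate early and heat shock genes, 16 rose and 3 fell, also over the list alone, with a median of 1.53 (camera adjusted p = 4.8e-04, or adjusted p = 0.266 with an estimated correlation). Atf3, a stress-induced factor, rose by 3.21 ± 0.18, Klf6 and Klf2 by 1.98 ± 0.08 and 1.96 ± 0.11, and the haem oxygenase Hmox1 by 1.53 ± 0.10.

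Of 13 mitochondrially encoded genes, 12 rose and 0 fell, also over the list alone, with a median of 0.52 (camera adjusted p = 6.2e-04, or adjusted p = 0.554 with an estimated correlation), but the median was −0.06 under quantile normalization. The complex I subunit mt-Nd3 rose by 0.97 ± 0.07, and mt-Co3, a subunit of cytochrome oxidase, by 0.72 ± 0.08, which turned to −0.22 under quantile normalization. The 31 nuclear respiratory chain genes, of which 3 rose and 15 fell (3 and 14 over the list alone), did not pass as a list (median −0.11, camera adjusted p = 0.127). They passed with fry (adjusted p = 0.0105), with quantile normalization (0.00999), with library totals (0.00186) and without both libraries of replicate 2 (0.0394). Cycs, cytochrome c, and the ATP synthase subunit Atp5b fell (−0.49 ± 0.06 and −0.39 ± 0.05), and Sdhb, a subunit of succinate dehydrogenase, rose by 0.33 ± 0.04, a rise that was lost with library totals (0.09, adjusted p = 0.0761).

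The genes of E proteins, the factors that Id2 inhibits, were lower, and of the genes of their inhibitors only Id2 rose under every alternative. The E-protein genes Tcf3, Tcf4 and Tcf12 fell (−0.54 ± 0.08, −1.23 ± 0.08 and −0.27 ± 0.04, adjusted p = 2.5e-04, 1.5e-06 and 4.5e-04). Id2, at chromosome 12 from 25093799 to 25097140, went from 27.7 ± 5.32 to 86.4 ± 5.92 CPM, a change of 1.66 ± 0.13 (adjusted p = 3.4e-06). Id1 rose by 0.41 ± 0.14 (adjusted p = 0.025) with overlapping libraries, a call lost with library totals (0.17, adjusted p = 0.293) and without untreated replicates 2, 3 or 4 or doxycycline replicates 1 or 3 (adjusted p from 0.0509 to 0.0682). Id3 differed by 0.62 ± 0.37 (adjusted p = 0.168), and by the same size with adjusted p = 0.0348 in the fit with the replicate block. As a list of 6 genes, 2 rose and 3 fell, also over the list alone, and the list did not pass (median 0.07 but camera direction down, adjusted p = 0.716), although it passed downward with fry (adjusted p = 0.0105).

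Genes of lymphoid and plasmacytoid dendritic cells, many of which E proteins activate, did not pass camera as lists. Both passed upward with fry (adjusted p = 7.3e-05 and 0.0281). Fry does not set a list against other genes, and 21 of the 25 tested lists passed it, so these passes do not set the lists apart. Of 8 lymphoid E-protein targets, 5 rose and 2 fell, also over the list alone, with a median of 0.59 against a mean of −0.06 (camera adjusted p = 0.213). Il7r, the interleukin-7 receptor, rose by 3.09 ± 0.15, Notch1 by 0.85 ± 0.08 and the cell cycle inhibitor Cdkn1a by 0.78 ± 0.08, whereas Rag2 fell. Of 19 plasmacytoid dendritic cell genes, 9 rose and 3 fell, also over the list alone (median 0.36, camera adjusted p = 0.118). The sensor Tlr7 rose by 2.57 ± 0.18, and the transcriptional regulators Cbfa2t3 and Runx2 fell (−1.89 ± 0.11 and −1.34 ± 0.08). This list passed with library totals (adjusted p = 0.0221) and with the stricter floor on low values (0.0369).

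The remaining lists did not pass camera. Of 30 integrated stress response genes, 9 rose and 11 fell (11 and 11 over the list alone), with a median of −0.11, a mean of 0.12 and adjusted p = 0.716; Psat1 and Shmt2, enzymes of serine metabolism, and the amino acid transporter Slc7a5 fell (−1.30 ± 0.06, −1.18 ± 0.07 and −1.13 ± 0.07). Of 23 glycolysis genes, 4 rose and 3 fell (1 and 0 over the list alone), with a median of 0.10 and adjusted p = 0.539, the glucose transporter Slc2a3 rising by 1.45 ± 0.29. Of 22 cholesterol synthesis genes, 4 rose and 7 fell, also over the list alone (median −0.07, adjusted p = 0.481), with Dhcr7, an enzyme of the last step, lower at −0.68 ± 0.07. Of 13 MHC class II genes, 5 rose and 3 fell, also over the list alone (median 0.25, adjusted p = 0.270, or 0.0073 with fry, upward); Ctss, a protease that trims the invariant chain, and the costimulators Cd86 and Cd80 rose by 3.06 ± 0.20, 2.08 ± 0.14 and 2.66 ± 0.25, and H2-Oa fell by 0.97 ± 0.18.

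Markers of other cell types were few among the measured genes, and their counts were the same over the list alone. Of 6 mast cell markers, 1 rose and 4 fell (median −0.82, adjusted p = 0.270, or 0.00746 with fry, downward), including Kit, a receptor that progenitors share, which fell by 3.72 ± 0.31. Of 7 megakaryocyte markers, 3 rose and 2 fell (median −0.05, adjusted p = 0.590, or 7.5e-04 with fry, upward), Vwf rising by 2.29 ± 0.09 and the integrin Itga2b falling (−2.24 ± 0.31). Of 5 T cell markers, 2 rose and 1 fell (median −0.55 but camera direction up, adjusted p = 0.716). Lists with fewer than 5 measured genes were not tested: of 2 B cell markers 1 rose, Cd22, by 2.53 ± 0.29, of 3 NK cell markers 1 fell, the 1 erythroid marker fell, and of 3 stromal and endothelial markers 2 fell, among them the adhesion molecule Pecam1, at −1.74 ± 0.09. For every gene named in this comparison as having risen or fallen, other than Id1 and Nras, all 4 doxycycline libraries lay beyond all 4 untreated ones, with adjusted p-values of at most 0.0018. In all, 14 of 25 tested lists passed, 10 upward and 4 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.107) and 21 with fry.

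**Figure D2:**
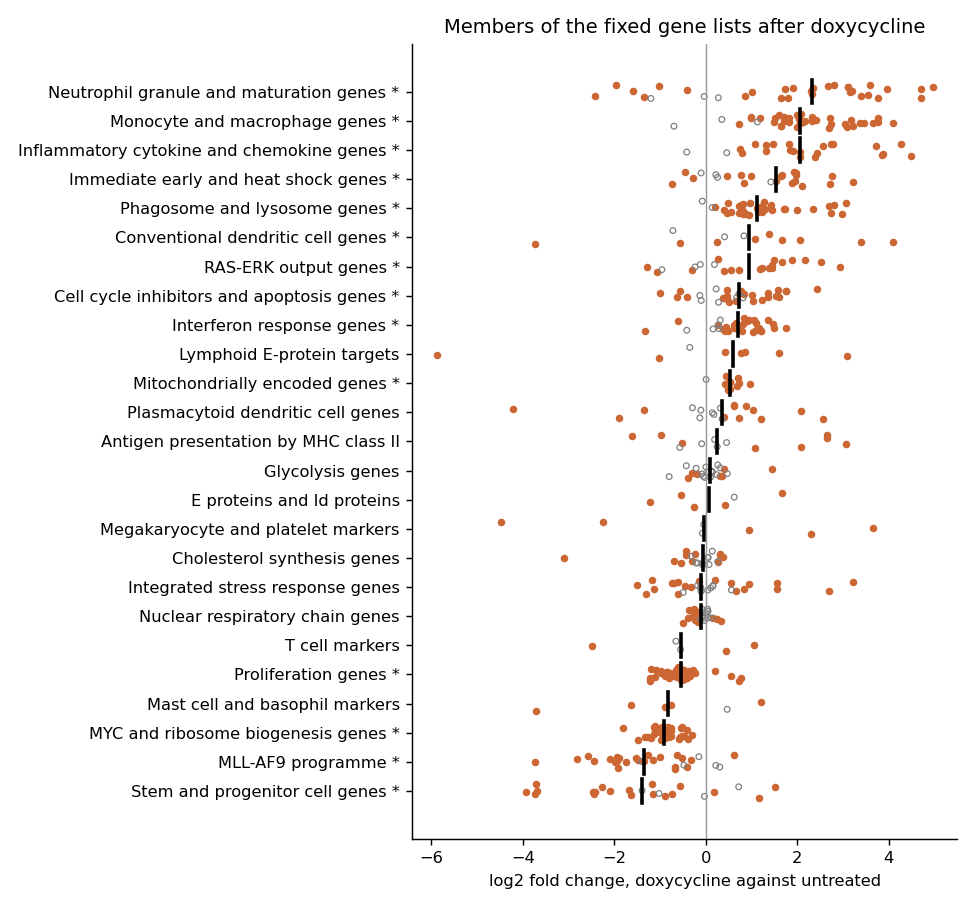
Log2 fold change after doxycycline (horizontal axis) for each measured gene of the lists; filled orange points passed limma's test at an adjusted p under 0.05, open grey points did not, black bars are list medians and an asterisk marks lists past camera's test. Monocyte, lysosome and inflammatory genes lie to the right (medians 2.06, 1.12 and 2.05) and MLL-AF9 programme and MYC genes to the left (medians −1.34 and −0.90); mitochondrially encoded genes, at 0.52, had a median of −0.06 under quantile normalization.

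The next comparison asked which genes changed 2 days after transduction with Id2. Id2 transcripts rose 36.2-fold, from 36.1 ± 13.6 CPM (SD, n = 3) in control-GFP cells to 1283 ± 340 CPM (n = 3) in Id2-GFP cells, a level well above the 86.4 CPM reached after doxycycline in the other table. Beyond Id2 and its pseudogene Gm6175, no gene passed the threshold in the fit without pairing. With the replicate block, 35 genes passed, among them Pacsin1, Gfi1b, Il12a and Mpo, which were lower, and Ctss, Mmp8 and Ms4a6c, which were higher. Single MLL-AF9 targets did not change detectably: Hoxa9, Meis1, Myb and Myc differed by 0.19 ± 0.27, 0.42 ± 0.25, −0.14 ± 0.23 and −0.04 ± 0.42. These changes were within the spread between libraries in the fit without pairing. Nor did these genes pass with the replicate block.

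The change of Id2 was 5.18 ± 0.31 (adjusted p = 0.0026), higher in 3 of 3 libraries, with 392 to 692 reads in control-GFP and 13658 to 23504 in Id2-GFP libraries. Its exact two-sided permutation p, with the pairing ignored, was 0.1, the smallest that 3 against 3 libraries allow. After adjustment over the 8 tests it was 0.16. Gm6175, a processed pseudogene at chromosome X from 100585009 to 100585408, rose by 6.76 ± 0.41 (adjusted p = 0.0026), with 1 to 3 reads in control-GFP and 190 to 307 in Id2-GFP libraries. Its transcript of 400 bases matches Id2 mRNA at 91.6% identity from base 30 to 400, over 380 aligned positions with gaps counted. Its reads may therefore be shared with Id2, and its own change is uncertain. At an unadjusted p under 0.05 there were 357 genes among 14563, fewer than the 1 in 20 that chance gives. The groups did not overlap for 1012 genes (6.95%), where chance gives 10% for 3 against 3 libraries. Without Id2-GFP replicate 1 no gene passed, and the changes of Id2 and Gm6175 were then 5.17 and 6.68, both with adjusted p = 0.125; without Id2-GFP replicate 3 only 1 gene passed, Gm6175 being at 6.63 (adjusted p = 0.077), and without control-GFP replicate 3 there were 3, Fam65a having joined (adjusted p = 0.0403).

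Mll1, Mllt3 and Nras, the genes carried by the other vectors, did not differ detectably. Mll1 was at 3377 ± 2671 and 3107 ± 1460 CPM and Mllt3 at 505 ± 249 and 431 ± 228 CPM, with changes of 0.10 ± 0.61 and −0.24 ± 0.43. Exact permutation p-values were 1 for Mll1, 0.5 for Mllt3 and 0.9 for Nras. The partners of Id2 were also within the spread: Tcf3, Tcf4 and Tcf12 differed by −0.07 ± 0.16, 0.29 ± 0.19 and 0.22 ± 0.26, and Id1 and Id3 by −0.50 ± 0.35 and −0.31 ± 1.57. All these genes had limma adjusted p = 0.998 in the fit without pairing, and they did not pass with the replicate block either.

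Control-GFP replicate 3 stood apart from the other 5 libraries of its table. It lay at 66.3 on the first principal component (61.3% of the variance), where the others lay between −28.6 and 8.73. Ribosomal protein genes took 8.51% of its reads against 3.39 to 5.24% in the others, 34 genes had 0 reads against 1 to 13, and 3343 genes differed over 2-fold from the mean of the other controls. The median SD of a gene within a group was 0.33 in this table against 0.12 in the doxycycline table.

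In the fit with the replicate block, 16 genes rose and 19 fell, each in the same direction in 3 of 3 pairs. Pacsin1, a cytoplasmic adaptor of plasmacytoid dendritic cells and neurons at chromosome 17 from 27655509 to 27711482, went from 17.2 ± 7.79 to 1.53 ± 0.608 CPM, a change of −3.43 (adjusted p = 7.0e-04 with the replicate block, 0.537 without). Also lower were Gfi1b, a repressor of the erythroid and megakaryocytic lineages, at −1.71 (adjusted p = 0.0311), the granule enzyme Mpo at −1.74 (0.0359), the lipoxygenase Alox5 at −1.54 (0.0359) and the adhesion receptor Gpr56 at −1.39 (0.0324). The cytokine subunit Il12a was at −1.30 (0.0311), the chemokine receptor Cx3cr1 at −1.38 (0.0359) and the heparan sulphate proteoglycan Sdc4 at −2.57 (0.0307), and Fam65a and Fam212a were at −1.51 and −1.76 (both 0.0173). Higher were the neutrophil collagenase Mmp8 by 1.96 (0.0104), the lysosomal protease Ctss by 1.32 (0.0324), the purine receptor P2rx7 by 1.43 (0.0407), the membrane proteins Ms4a4b, Ms4a6c and Myof by 2.82, 1.33 and 1.72 (0.0227, 0.0407 and 0.0334), Fam129b by 1.16 (0.0442) and the ligand Wnt10b by 1.37 (0.0444). Without pair 1, pair 2 or pair 3 the replicate block gave 95, 171 and 468 genes. All 35 genes were among the 468, in a fit that reuses the same libraries and has little residual information. Their same sign there follows from their shared direction in every pair, so it is not a separate check. Il7r and Siglech, at −1.57 and −2.37, did not pass with the block of all pairs (adjusted p = 0.0788 and 0.0843). In the replicate block with a pair left out, Il7r passed without pair 2 or 3 (1.9e-04 and 1.3e-15) and Siglech without pair 1 or 3 (0.0108 and 0.0462). Such fits have little residual information and lean on the variance shared across genes, so these calls do not outweigh the fit of all pairs.

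**Figure D3:**
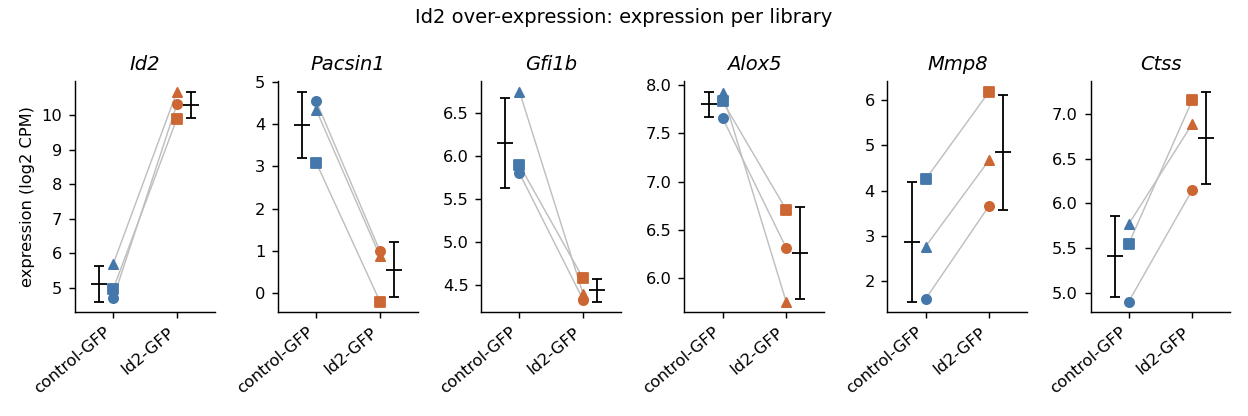
Expression of named genes in the 3 control-GFP and 3 Id2-GFP libraries, in log2 CPM on the vertical axis; each point is a library, marker shapes and grey lines join libraries with the same replicate number, and bars beside the points are the mean ± SD. Id2 lies at 10.29 ± 0.39 in Id2-GFP against 5.11 ± 0.52 log2 CPM in control-GFP libraries, and Pacsin1 at 0.56 ± 0.66 against 3.98 ± 0.79.

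Proliferation genes were lower as a group after Id2. Of 43 genes, 42 lay below 0, with a median of −0.43 (camera adjusted p = 2.5e-15, or adjusted p = 0.571 with an estimated correlation), although 0 passed singly, also over the list alone. The cyclin Ccnd3 differed by −0.79 ± 0.16, and the replication genes Mcm3, E2f1 and Cdt1 by −0.52 ± 0.23, −0.45 ± 0.19 and −0.43 ± 0.16. The median deviation of control-GFP replicate 3 from the other controls was −0.08 in this list. No single library left out ended this call.

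The MLL-AF9 programme, whose genes fell after doxycycline, was slightly higher after Id2, at a median of 0.26 over 28 genes (camera adjusted p = 0.0020, or adjusted p = 0.571 with an estimated correlation). None passed singly, also over the list alone, and Hoxa3 and Hoxa6 differed by 0.74 ± 0.26 and 0.89 ± 0.34. Control-GFP replicate 3 deviated by a median of −0.46 in this list, and without it the median was 0.04 (adjusted p = 0.269). The 29 integrated stress response genes had a median of −0.22 (camera adjusted p = 0.0020, or adjusted p = 0.844 with an estimated correlation) and 0 passed singly, also over the list alone, Psat1 and Atf4 differing by −0.61 ± 0.27 and −0.37 ± 0.19. There control-GFP replicate 3 deviated by 0.47, and without it the median was −0.07 (adjusted p = 0.871).

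Further lists passed with small medians. Without the block none of their members passed singly, also over the list alone. With it 1 monocyte gene fell (2 rose and 2 fell over the list alone). Each list call was lost with an estimated correlation (adjusted p = 0.844 for each). The 31 nuclear respiratory chain genes, such as Cox5a at −0.45 ± 0.31, had a median of −0.18 (camera adjusted p = 0.0035), the 40 MYC and ribosome biogenesis genes, such as Odc1 at −0.45 ± 0.28, one of −0.17 (0.0054), and the 22 cholesterol synthesis genes, such as Cyp51 at −0.50 ± 0.26, one of −0.19 (0.0054). Control-GFP replicate 3 deviated by medians of 0.79, 0.50 and 0.41 in these lists, and without it their medians were 0.04, −0.03 and −0.07 (adjusted p = 0.269, 0.848 and 0.594). The 13 mitochondrially encoded genes, such as mt-Nd4l at 0.75 ± 0.51, had a median of 0.32 (camera adjusted p = 0.0045), and the 35 monocyte genes one of 0.23 (0.0234). In these, control-GFP replicate 3 deviated by −0.42 and −0.06, and without it the medians were 0.18 and 0.19 (adjusted p = 0.212 and 0.214). Mitochondrial genes took 7.09% of reads in Id2-GFP replicate 2 against 3.15 to 4.35% in the other libraries. Without that library the medians of the mitochondrial, monocyte, MYC, cholesterol and nuclear respiratory lists were −0.03, −0.02, −0.01, −0.09 and −0.16 (adjusted p = 0.987, 0.658, 0.987, 0.576 and 0.121), and without control-GFP replicate 1 the monocyte median was 0.12 (adjusted p = 0.155).

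The E and Id protein list, of 6 genes, passed on Id2 itself, the only member that rose (median 0.08, camera adjusted p = 0.0239, or adjusted p = 0.571 with an estimated correlation, 1 gene over the list alone). The median was −0.01 without control-GFP replicate 3, which deviated by −0.09, 0.20 without Id2-GFP replicate 1 and 0.15 without Id2-GFP replicate 2, and the call was then lost (adjusted p = 0.214, 0.0575 and 0.141). With the replicate block, neutrophil genes (28 genes, median 0.20, adjusted p = 0.0144 against 0.152 without it), mast cell markers (6 genes, median −0.42, 0.0170 against 0.225) and megakaryocyte markers (5 genes, median −0.53, 0.0389 against 0.0704) passed as well, and each call was lost with an estimated correlation in that fit (adjusted p = 0.748 for each). In the fit with the replicate block 1 neutrophil gene rose and 1 fell (7 and 3 over the list alone), and no mast cell or megakaryocyte marker passed (0 rose and 1 and 3 fell over the list alone). Without the block 0 members of these lists passed, also over the list alone. Control-GFP replicate 3 deviated by −0.61 in the neutrophil, −1.11 in the mast cell and 0.02 in the megakaryocyte list. The examples Anxa1, Kit and Itga2b differed by 0.65 ± 0.23, −0.76 ± 0.52 and −1.14 ± 0.38.

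Lists of lymphoid and dendritic cell genes did not pass after Id2, and the counts of their members given here are without the block. The 8 lymphoid targets had a median of −0.03 (camera adjusted p = 0.573), the 19 plasmacytoid dendritic cell genes one of 0.08 against a mean of −0.25 (0.601), and 1 gene fell over the list alone in each. The 12 conventional dendritic cell genes, of which Id2 rose (1 also over the list alone), had a median of −0.09 against camera direction up (0.152), and the 12 MHC class II genes a median of −0.02 (0.326, 1 rose over the list alone). Control-GFP replicate 3 deviated by 1.66 and 0.99 in the last pair of lists, and without it they passed at medians of 0.43 and 0.27 (adjusted p = 0.00333 and 0.00994). They also passed without Id2-GFP replicate 1, at 0.30 and 0.28 (adjusted p = 0.0299 and 0.0192). The conventional dendritic cell list passed too with array weights (adjusted p = 0.00692) and with the replicate block without pair 1, 2 or 3 (0.0015, 0.0406 and 9.1e-08), where its medians were 0.06, −0.19 and −0.05. Id2 itself, at 5.18, is a member of this list. The MHC class II list passed without pair 3, unblocked (0.0137) or with the replicate block (7.8e-04).

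Of the lists left, none passed. Without the block none had a member that passed singly, over all genes or over the list alone, except 2 genes that fell among 2 stromal markers over the list alone. With the replicate block, 1 lysosome gene rose over all genes and 3 over the list alone. Over the list alone in that fit, 1 inflammatory, 1 immediate early, 1 glycolysis and 1 B cell gene rose, and 1 stem cell, 2 erythroid and 2 stromal genes fell. Medians were −0.07 for 22 stem cell genes (camera adjusted p = 0.964), −0.08 for 30 cell cycle inhibitor and apoptosis genes (0.601), −0.11 for 21 RAS-ERK output genes (0.648), −0.14 for 23 immediate early genes (0.648), −0.21 against a mean of 0.05 for 16 inflammatory genes (0.764), 0.04 for 35 lysosome genes (0.225) and 0.07 for 6 T cell markers (0.861). The 33 interferon response genes had a median of −0.03 (0.895) and depended on single libraries: control-GFP replicate 3 deviated by 1.49, and the median was 0.43 without it (adjusted p = 1.6e-05), 0.28 without Id2-GFP replicate 1 (0.0192), −0.34 without control-GFP replicate 2 (0.032) and −0.33 without Id2-GFP replicate 3 (0.00372). The 23 glycolysis genes had a median of −0.12 (0.573), in which control-GFP replicate 3 deviated by 0.78, and −0.39 without control-GFP replicate 1 (adjusted p = 3.96e-04) and −0.29 without pair 1 (0.0268). The lysosome list passed without Id2-GFP replicate 3 (0.13, adjusted p = 2.6e-04), without pair 3 (0.09, 0.00114) and under quantile normalization (0.10, 0.0236). The neutrophil list passed without control-GFP replicate 2 or Id2-GFP replicate 3 (0.45 and 0.48, adjusted p = 0.0020 and 5.8e-04). Without control-GFP replicate 3 the mast cell and megakaryocyte lists passed (−0.74 and −0.52, adjusted p = 0.00994 and 0.0392). The megakaryocyte list passed with each other scaling as well (adjusted p from 0.033 to 0.0461). The stem cell list passed only with the replicate block without pair 3 (−0.13, adjusted p = 0.00108). Lists with under 5 measured genes were not tested: 2 B cell, 3 NK cell, 4 erythroid and 2 stromal markers had medians of 0.57, 0.15, −1.13 and −0.69, and control-GFP replicate 3 deviated by 1.67 in the NK cell and 3.84 in the erythroid markers. In all, 9 of 25 tested lists passed, 4 upward and 5 downward, 0 with an estimated correlation and 0 with fry (lowest adjusted p = 0.0613).

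The last comparison asked whether Id2 moves the genes that doxycycline moves in these cells, from libraries that share no control. Genes that rose after doxycycline were on balance slightly higher after Id2, and genes that fell were slightly lower. Among the 200 genes that rose with the smallest p, 196 were measured after Id2, with a median of 0.24, and 78.6% lay above 0 (camera adjusted p = 1.2e-14, or adjusted p = 0.150 with an estimated correlation). Among the 200 that fell, 198 were measured, with a median of −0.23, and 83.3% lay below 0 (camera adjusted p = 5.7e-14, or adjusted p = 0.165 with an estimated correlation). Without Id2-GFP replicate 2 the medians were 0.11 and −0.11, and without control-GFP replicate 3 they were 0.22 and −0.21.

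Across the 12647 genes measured in both tables, the 2 sets of fold changes correlated at a Pearson r of 0.355 and a Spearman rho of 0.372, and 63.8% had the same sign. This is a correlation across genes, which are not independent replicates, and it was 0.192 without Id2-GFP replicate 2. With an estimated correlation, 0 lists passed camera in either comparison. Of the 5 lists past camera with the preset correlation in both comparisons, 4 had the same direction. Of these, the monocyte, MYC and mitochondrial lists lost their calls after Id2 without control-GFP replicate 3 (adjusted p = 0.214, 0.848 and 0.212) and had medians of −0.02, −0.01 and −0.03 without Id2-GFP replicate 2. The mitochondrial list was at −0.06 after doxycycline under quantile normalization. The MLL-AF9 programme had medians of −1.34 after doxycycline and 0.26 after Id2. Its value after Id2 rested on control-GFP replicate 3, since it was 0.04 without that library (adjusted p = 0.269) and −0.01 without pair 3, and its call was lost with an estimated correlation (adjusted p = 0.571). Lists that passed after doxycycline only and had a median of the opposite sign after Id2 were the inflammatory (2.05 and −0.21), immediate early (1.53 and −0.14), RAS-ERK output (0.95 and −0.11), conventional dendritic cell (0.95 and −0.09), cell cycle inhibitor (0.72 and −0.08) and interferon response genes (0.71 and −0.03). Those with the same sign were the neutrophil (2.31 and 0.20), lysosome (1.12 and 0.04) and stem cell genes (−1.39 and −0.07). The difference between the comparisons was not tested. After Id2 the conventional dendritic cell list had a mean of 0.41 and the inflammatory list one of 0.05. Without control-GFP replicate 3 the conventional dendritic cell and interferon lists passed upward, both at 0.43 (adjusted p = 0.00333 and 1.6e-05).

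Without the block, Id2 was the only gene past the threshold in both comparisons. With the replicate block in both fits, 12 of the 13 genes that rose after Id2 and were measured in both tables also rose after doxycycline, where 4.27 were expected (Fisher's exact test, adjusted p = 5.7e-05 over 4 directions). These included Id2, Ctss, Myof, P2rx7 and Fam129b, which after doxycycline rose by 1.66 ± 0.13, 3.06 ± 0.20, 3.67 ± 0.20, 1.53 ± 0.09 and 2.14 ± 0.07. The rise of Id2 after transduction with Id2 was set by the design, yet it counts in this overlap. Fisher's test also treats genes as independent, which genes regulated together are not. Of the 19 genes that fell after Id2, 15 also fell after doxycycline, where 7.07 were expected (adjusted p = 7.9e-04), including Pacsin1, Gfi1b, Il12a, Fam65a and Fam212a, which after doxycycline were at −4.21 ± 0.47, −4.54 ± 0.25, −3.91 ± 0.27, −1.8 ± 0.10 and −1.64 ± 0.12. In opposite directions, Cx3cr1, Sdc4 and Alox5 rose after doxycycline (1.52 ± 0.23, 1.49 ± 0.25 and 0.75 ± 0.17) and fell after Id2, 3 genes where 6.25 were expected (adjusted p = 0.144). Wnt10b fell after doxycycline (−3.06 ± 0.48) and rose after Id2, 1 gene where 4.84 were expected (adjusted p = 0.0532). Without pair 3 of the Id2 table, an alternative chosen after the data were seen and with little residual information, 197 of 239 genes rose in both (78.6 expected) and 141 of 212 fell in both (78.9 expected).

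**Figure D4:**
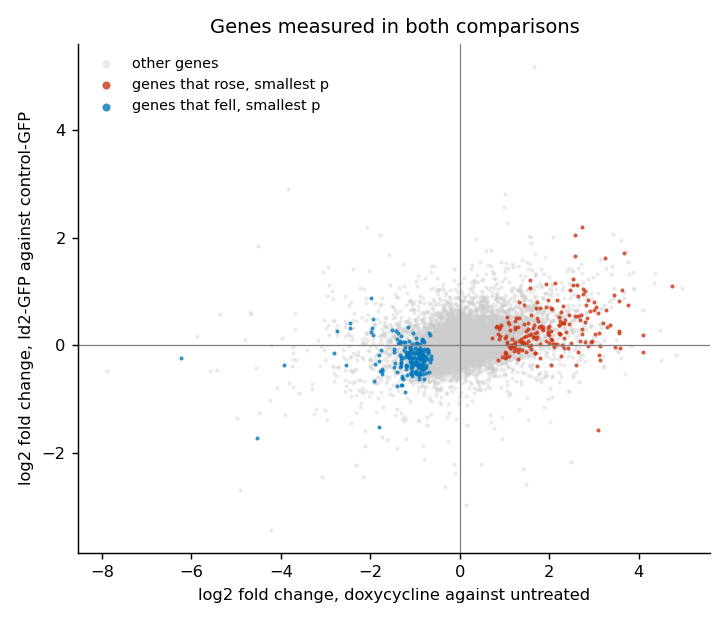
Log2 fold change after doxycycline (horizontal axis) against log2 fold change after Id2 (vertical axis) for the 12647 genes measured in both tables; red and blue points are the genes with the smallest p among those that rose and fell after doxycycline. The red points have a median of 0.24 and the blue points one of −0.23 on the vertical axis, where most changes are small.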

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

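All tests of technical explanations in this part were set before their results were seen, except the test of a shared origin of the libraries numbered 3, which was chosen afterwards. For the named genes and for library measures such as reads and scaling factor in the doxycycline table, single libraries far from the others were sought by Dixon's criterion. Among the 242 groups of 4 libraries tested, 8 were found where chance gives about 1 in 20 groups, or 12.1.

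In the untreated group, replicate 1 lay apart for Tcf4 (7.68 log2 CPM against 7.88 to 7.91 in the others), Klhl30 (−1.19 against 0.46 to 0.70) and Cd86 (0.44 against 0.76 to 0.81). Untreated replicate 2 was low for Cad (7.44 against 7.57 to 7.58) and untreated replicate 4 high for Anxa1 (7.81 against 7.31 to 7.39). In the doxycycline group, replicate 3 was low for Trem2 (8.56 against 8.80 to 8.84) and high for Kit (2.97 against 1.55 to 1.77), and replicate 4 was low for Id3 (0.0228 against 0.88 to 1.00). None of these genes changed its call when that library was left out.

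Control-GFP replicate 3 stood apart from the other libraries of its table. Its deviation from the other controls correlated across genes with transcript length at a Spearman rho of −0.514, so a bias by transcript length, which the quality of the RNA may produce, stays open. With GC content the rho was 0.159, between the bounds of 0.1 and 0.3 set for that test, and GC bias cannot be told apart from it. The deviation also correlated across genes with that of Id2-GFP replicate 3 (0.557), so an origin shared by the libraries numbered 3 stays open too. That test largely repeats the pairing check, in which pairs 1 and 2 correlated as well (0.502 and 0.501). It therefore cannot tell why this library in particular stands apart. Erythroid (3.84), NK cell (1.67), conventional dendritic cell (1.66), interferon response (1.49), MHC class II (0.99) and mast cell genes (−1.11) deviated in it as well, so a difference in cell composition or interferon response stays open and was not tested.

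Gm6175 rose with Id2 in the Id2-GFP libraries. Its transcript matches Id2 mRNA at 91.6% identity, between the bounds of 80% and 95% set for that test, so reads shared with Id2 may account for it and the test does not decide. Its reads were 1.30 to 1.58% of those of Id2 in Id2-GFP libraries and 0.145 to 0.765% in control-GFP libraries. Expression of the pseudogene itself was not tested.

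The Id2 fold changes followed the doxycycline fold changes with r = 0.355 across genes. The tables argue against control-GFP replicate 3 as the only source, since r was 0.267 without it. Without the proliferation and MYC lists and the 500 genes most correlated with them, r was 0.343 over 12069 genes, so it did not rest on the removed genes. That test cannot decide on a wider growth programme. It removed only genes that move in the same direction, and 8733 genes changed after doxycycline. The tables also argue against trends with gene length, GC content and mean level, since r was 0.358 over 12520 genes after removing them. The 6 libraries make 10 splits, too few for a share under 0.05, and the real split gave 0.355 and the highest other split 0.333. An effect of Id2 on genes that MLL-AF9 controls may be involved, but r fell to 0.192 without Id2-GFP replicate 2, and the explanation stays open until Id2 is removed from cells during MLL-AF9 withdrawal, which was not analysed here.

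Other splits of the libraries were tested for each count. After doxycycline, the real split gave 8733 genes and the highest other gave 1, so 1 of 35 splits was as large. That is the smallest share these splits allow, and most of them ignore the pairing. The 8 that part every pair are too few for a share under 0.05, so the splits alone do not exclude chance. For lists after doxycycline, 9 of 35 splits gave as many as the real 14, the highest other being 19, so chance is not excluded for the count of lists by that test. For genes after Id2, the 10 splits are too few for a share under 0.05; the real split gave 2 and the highest other 0, and 1 split of 10 was as large. For lists after Id2, the splits are again too few; the real split gave 9 and the highest other 11, and 7 of 10 were as large. Among splits that part every pair, 8 after doxycycline and 4 after Id2, the fit with the replicate block gave 9326 and 35 genes for the real split and 0 for the highest other, and those others exchange the groups in some pairs only.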

How the results depend on the processing

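Scaling by library totals and by median-of-ratios factors, voom weights, the replicate block with a pair left out, and the withdrawal sets and overlaps without single libraries or pair 3 were chosen after seeing the data. The count-model test planned for recovered reads was not run, since the deposited unit is log2, and the pseudocount alternatives did not apply. Of 164 named gene results, 132 kept their call under every alternative run, as did 11 of 50 list results. Those that passed also kept their direction. For results that did not pass, direction was not compared. The cause of the changes given here was not tested, unless the alternative itself has fewer libraries or a stricter criterion.

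After doxycycline, 8733 genes passed, 2055 with a change of at least 2-fold, 7563 to 8616 without single libraries or pairs and 9614 with library totals. The 14 lists became 0 with an estimated correlation (lowest adjusted p = 0.107), 21 with fry and 13 to 15 without single libraries or pairs. Nras turned to −0.0304 and mt-Co3 to −0.22 under quantile normalization.

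After Id2, 2 genes passed, and 35 with the replicate block, 95, 171 and 468 with the replicate block without pair 1, 2 or 3, 3 with array weights and 0 to 3 without single libraries or pairs. Exchanging the labels of pair 2 in the block of pairs 1 and 2 gave 0 genes. Apart from the calls given with the replicate block in the results, the block of all pairs changed no other call of a named gene or list. Genes that passed only in a block without a pair were Itga2b (without pair 1, 2 or 3, adjusted p = 0.0286, 0.0133 and 1.0e-05), and without pair 3 Hoxa3 (0.0248), Ccnd3 (0.00633), Cebpa (0.0276), Anxa1 (0.0133) and Kit (1.4e-08), besides Il7r and Siglech. Blocks with a pair left out have little residual information and lean on the variance shared across genes. The change of Id2 was 4.96 to 5.46 without single libraries or pairs. The 9 lists became 0 with an estimated correlation, 0 with fry, 3 with array weights and 3 to 12 without single libraries or pairs. With array weights, the medians turned to 2.3e-04 (MYC), 0.28 (interferon) and 0.0294 (nuclear respiratory). Without single libraries or pairs, medians ranged from −0.38 to 0.43 (interferon), −0.39 to 0.10 (nuclear respiratory), −0.0167 to 0.39 (monocyte), −0.32 to −0.00942 (MYC), −0.0291 to 0.57 (mitochondrial) and −0.43 to −0.0302 (integrated stress response). In the replicate block of pairs other than 3, they turned to 0.16 (interferon), −0.0302 (integrated stress response), 0.10 (nuclear respiratory) and 0.19 (glycolysis).

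The withdrawal sets kept their direction in the Id2 table under every alternative, at 0.09 to 0.33 for genes that rose and −0.36 to −0.11 for genes that fell, and lost their calls with an estimated correlation only (0.24 with adjusted p = 0.150, −0.23 with adjusted p = 0.165). Without single libraries they were 0.11 to 0.33 and −0.36 to −0.11. Depth limits the genes with few reads. Where a group lies below 3 reads per library (0.152 CPM after doxycycline), the size of a change is uncertain. In the simulated data for the Id2 table, 10 of 67 changes of 1.5-fold were recovered. Those data gave every gene the same spread and had no pairs.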

Other observations

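Control-GFP replicate 1 and 2 had 768 and 1593 genes over 2-fold from the mean of the other controls, against 3343 for control-GFP replicate 3, and Id2-GFP replicate 3 had 1136 from the other Id2-GFP libraries. Ribosomal protein genes deviated by a median of 1.40 in control-GFP replicate 3.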
